A study of Rattus norvegicus with 18 samples.

How the data were processed

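The deposited table of 31099 probe sets by 18 arrays was used, with no raw array files. Per the labels, total RNA of full-thickness colon was hybridised by Affymetrix protocols, and the authors normalized the arrays in Bioconductor with the affyPLM package. The version, the background method, the log base and whether all arrays were normalized together are not given in the sources used here; the deposited values range like log2 signals and were used as log2. Per the labels, the extraction entry reads Trizol for the 12 TNBS samples and names only a technical manual for the 6 controls. No other series, data type or sample was analysed here, and 0 columns of other samples were present.

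The 57 array control probe sets were left out of tests, which leaves 31042. Of these 20826 carry 1 gene symbol, 436 several and 9780 none listed. The single-symbol probe sets stand for 14217 genes, 4525 of them with more than 1 probe set, and 20764 of the single-symbol probe sets have a symbol found in the RefSeq table. A gene is represented by its single-symbol probe set with the highest mean over the 18 arrays. Probe sets called in the opposite direction exist for 5 genes, none of them named.

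Groups were control (6 arrays) and TNBS days 2, 5, 7 and 14 (3 arrays each). limma fitted 1 coefficient per group to all 18 arrays, so that they share 1 estimate of spread, with the default empirical Bayes prior and two-sided tests. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. Each day was compared with control, and days 5 with 2, 7 with 5, 14 with 7 and 14 with 2. A moderated F test covered the 4 differences from control, and the day with the largest deviation was counted for the probe sets it called. Overlaps between days were set against the product of list sizes over the number tested, against 20 simulations of unchanged groups on the shared controls, and against disjoint sets of 3 controls. The 3 prime minus 5 prime differences of Gapdh and beta-actin were compared by exact permutation tests.

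The comparisons, tests, 20 gene lists, 21 cell type lists and most alternatives were fixed before the data were examined. List shifts were tested with camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene, and adjusted over the 41 lists and 4 comparisons against control, and as a separate family over the 4 comparisons between days. Camera with an estimated correlation and fry were run beside it. A call adjusted over the list alone applies the Benjamini-Hochberg adjustment to the measured members of that list. Of the listed genes, 37 sit in more than 1 list.

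The planned scale was the deposited one. The array values then showed that control and TNBS arrays have different distributions, so after the values were seen it was decided to give levels against control after quantile normalization across the 18 arrays, which had been listed beforehand as another scale to try, and to speak of a rise or fall against control only for genes called the same way on both scales. The same condition applies to the counts adjusted over a list alone. Differences between days, and the calls among them, use the deposited values as planned. An F test among the 4 TNBS days, which uses no control array, was added for the same reason. Quantile normalization sets all arrays to 1 distribution, so a change shared by most genes would be removed by it.

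The named genes follow a rule fixed beforehand. Part a takes, for each day against control, the 6 genes with the largest increase and the 6 with the largest decrease among called genes whose day and control arrays do not overlap, and for each comparison between days the 3 and 3 largest. Part b takes from each list up to 3 members with the smallest adjusted p of the F test. Part c is a fixed panel of known colitis and colon genes, of which Mpo has no single-symbol probe set. Genes whose symbols begin with LOC or RGD, and probe sets with several or no symbols, are passed over in part a. Members that were called but lie outside this rule are counted and not named.

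Alternatives were quantile normalization, median centring, leaving out the lowest 50% or 25% of probe sets by mean, trend and robust empirical Bayes, a fit of only the 2 groups compared, array weights, replicate number as a block, 1 probe set per gene, adjusted p under 0.01, and leaving out each array in turn. Added after the data were seen were the same settings repeated on the quantile-normalized values, the requirement of both scales, list member counts without each array, and day 14 against day 2 without day 2 replicate 1. Calls were also counted over other splits of the same arrays: all 84 for each day against control, all 10 for each pair of days, and 100 random groupings for the F test.

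The procedure was tested on simulated data. For day 5 against control after quantile normalization, 200 of 31042 probe sets were changed. Of these 86.0% were recovered at a log2 change of 1, with 8 unchanged probe sets called, and 96.5% at a log2 change of 2, with 10. The simulated arrays had independent errors and an offset that quantile normalization removes by construction. Offsets of single probe sets and the condition of both scales were not simulated, so these rates do not carry over to the comparisons with control. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.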

Results

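Gene expression was measured in the colon of 18 rats to follow the course of colitis after trinitrobenzene sulfonic acid (TNBS), a hapten that inflames the bowel when it is given into the rectum together with ethanol. The control group was 6 rats that received saline, and 3 rats each were sampled on days 2, 5, 7 and 14 after 1 enema of 10 mg TNBS in 50% ethanol. Full-thickness colon was homogenised, so that epithelium, smooth muscle, nerves, vessels and leukocytes of the wall were read together, on 1 Affymetrix rat genome array per rat. Rats in the TNBS groups had been selected at each day on inflammatory markers, among them the activity of the neutrophil enzyme myeloperoxidase, so a high level of neutrophil genes is in part built into the groups. The labels name Trizol as the extraction method of the 12 TNBS samples and only a technical manual for the 6 controls, so extraction cannot be separated from treatment. No group received ethanol without TNBS, so effects of the 2 cannot be separated either, and the sample labels give no sampling day for the controls. The number of arrays limits the precision, and a gene value after a plus-minus sign carries the standard error of the linear model (SE) unless another error is named.

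The deposited values are on a logarithmic scale whose base and centring are not given, and they were read as log2. Column medians of the 6 control arrays, replicates 1 to 6, were 4.295, 4.283, 4.301, 4.268, 4.268 and 4.298. Those of replicates 1 to 3 were 5.032, 5.063 and 5.063 on day 2, 5.032, 5.075 and 5.041 on day 5, 5.048, 5.053 and 5.057 on day 7, and 5.049, 5.031 and 5.027 on day 14. The mean median was 0.762 higher in the TNBS arrays, and the upper quartile 0.810 higher, but the 99th percentile only 0.290 higher. As deposited, limma called 25703 of 31042 probe sets higher and 163 lower on day 2, 25104 and 340 on day 5, 24872 and 331 on day 7, and 26909 and 42 on day 14, so between 98.7% and 99.8% of calls against control were increases. After quantile normalization between 43.7% and 48.1% were, and after median centring between 20.6% and 22.7%. Levels against control are therefore given after quantile normalization, which leaves a median log2 change between -0.04 and -0.01 where the deposited values have 0.54 to 0.59. A gene is said to have risen or fallen against control only where limma called it the same way both as deposited and after quantile normalization. This condition is one-sided, because the offset of the deposited values lifts nearly all probe sets: it kept every call of higher after quantile normalization (2835, 3762, 3849 and 1741 on days 2, 5, 7 and 14) but 162 of 3065, 338 of 4493, 331 of 4951 and 42 of 1891 calls of lower. Small counts of falling genes against control are therefore in part set by the condition, and the balance of rises and falls is not a finding. List tests against control are likewise those after quantile normalization; of their 54 calls over the 4 days, 26 were also called the same way as deposited and 28 were not. Comparisons between days use the deposited values, in which the TNBS arrays have nearly the same distribution.

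**Figure D1:**
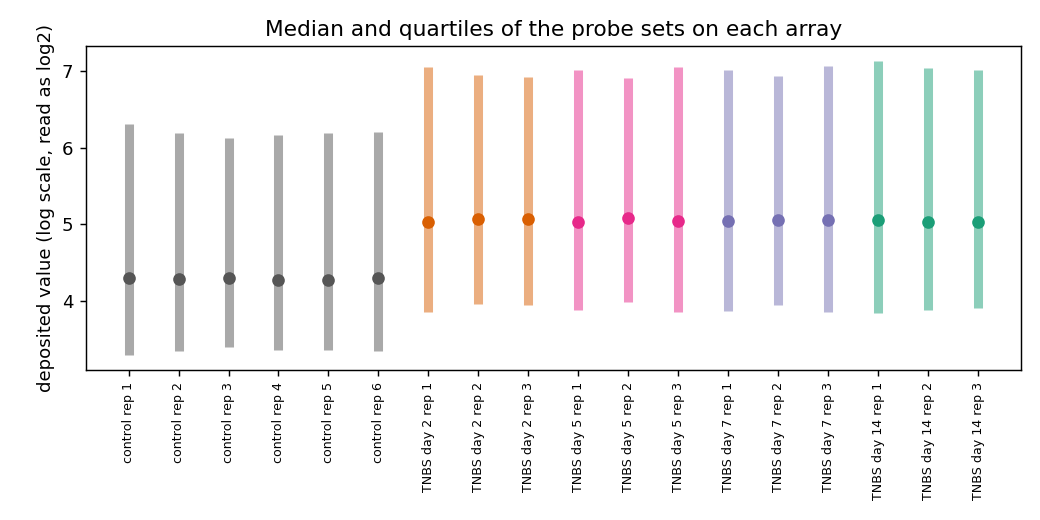
Median (point) and quartiles (bar ends) of the deposited log2 values of each of the 18 arrays, by group. Control medians lie between 4.268 and 4.301 and TNBS medians between 5.027 and 5.075, with no overlap.

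Probe sets along 2 transcripts, which serve as a reading of RNA quality, also gave different values in control and TNBS arrays, but in opposite directions, so they do not show a common difference in RNA quality. The 3 prime minus 5 prime difference of Gapdh, a glycolytic enzyme, was 0.03 ± 0.13 (SD, n = 6) in control and 0.46 ± 0.20, 0.69 ± 0.06, 0.60 ± 0.08 and 0.57 ± 0.13 (SD, n = 3) on days 2, 5, 7 and 14. That of beta-actin, a cytoskeletal protein, went the other way, from 2.02 ± 0.13 to 1.15 ± 0.30, 1.37 ± 0.04, 1.40 ± 0.10 and 1.13 ± 0.17. Each day differed from control in both transcripts in an exact permutation test (two-sided p = 0.0238, the smallest possible here, and 0.0298 after adjustment). Days 14 and 7 differed by -0.03 in Gapdh and -0.27 in beta-actin, with exact p = 0.9 and 0.1, where 0.1 is the smallest p that 3 against 3 allows.

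In a principal component analysis of the quantile-normalized values, the first component held 45.4% of the variance and ordered the groups. Control arrays scored between -52.3 and -38.6, day 14 arrays between -17.9 and -5.3, and day 5 and day 7 arrays between 18.4 and 69.5. Day 2 replicate 1 stood apart from the other day 2 arrays, at -14.9 against 32.1 and 37.0, and its mean correlation was 0.987 with the day 14 arrays and 0.970 with the other day 2 arrays.

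**Figure D2:**
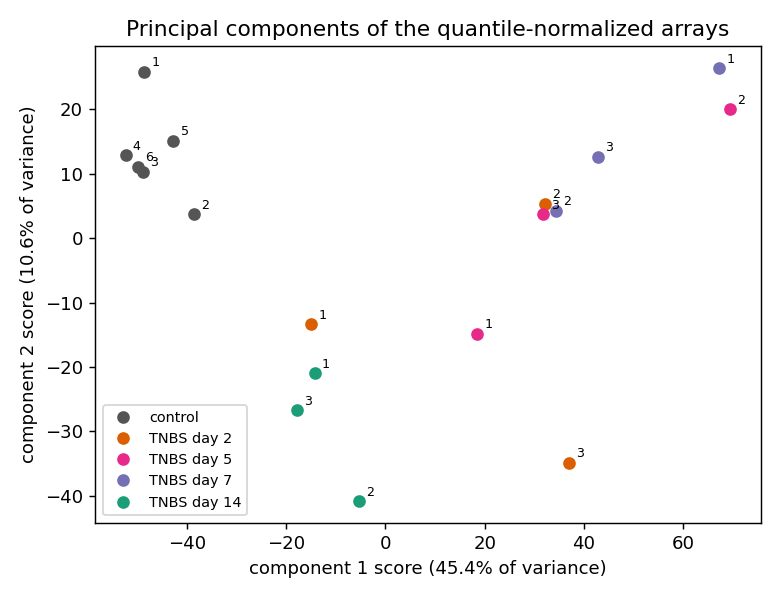
Scores of the 18 arrays on the first (45.4% of variance) and second (10.6%) principal components of quantile-normalized log2 values, coloured by group. The controls lie at the left, day 14 and day 2 replicate 1 next to them, and the other TNBS arrays to the right.

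The first comparison asked how far the colon departed from control 2 days after the enema. The largest increases were in genes of neutrophils and of the chemokines that attract them. S100a9 and S100a8, the subunits of the leukocyte protein calprotectin, rose by 6.26 ± 0.52 and 6.09 ± 0.61 on the log2 scale (n = 3 against 6, limma adjusted p = 2.38e-06 and 1.27e-05). The neutrophil chemoattractants Cxcl2 and Cxcl1 rose by 6.46 ± 0.55 and 4.42 ± 0.45, the iron-sequestering defence protein Lcn2 by 5.15 ± 0.66, and Plek, a signalling protein of platelets and leukocytes, by 4.16 ± 0.65 (adjusted p between 3.17e-06 and 0.000541). In the other direction Amn, a partner of the intestinal vitamin B12 receptor, fell by 2.33 ± 0.22, the retinol-binding protein Rbp7 fell by 3.00 ± 0.45, and the mast cell protease Mcpt1 fell by 2.56 ± 0.61 (adjusted p = 6.67e-06, 0.000375 and 0.00885). Quantile normalization gave 2835 probe sets higher and 3065 lower than control, and 2835 and 162 were called the same way on both scales.

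The neutrophil, macrophage, chemokine, cytokine and mucosal defence lists each held rising genes on day 2. Of 10 measured neutrophil markers 5 rose (5 adjusted over the list alone), among them the granulocyte growth factor receptor Csf3r at 2.17 ± 0.45; camera gave adjusted p = 0.000813, and adjusted p = 0.498 with an estimated correlation. Of 17 macrophage and monocyte markers 13 rose (13 adjusted over the list alone), led by the lysosomal glycoprotein Gpnmb at 3.67 ± 0.37. The macrophage list had camera adjusted p = 5.64e-08, and adjusted p = 0.375 with an estimated correlation. Chemokines rose in 7 of 20 cases (9 adjusted over the list alone), with Ccl3 at 2.90 ± 0.52. The chemokine list had camera adjusted p = 0.000599, and adjusted p = 0.302 with an estimated correlation. Among 23 cytokines and inflammatory mediators 8 rose (11 adjusted over the list alone): interleukin-1 beta, Il1b, by 3.52 ± 0.43, its decoy receptor Il1r2 by 3.36 ± 0.63 and its antagonist Il1rn by 1.78 ± 0.34. The cytokine and mediator list had camera adjusted p = 0.000686, and adjusted p = 0.594 with an estimated correlation. Mucosal defence and acute phase genes rose in 9 of 19 cases (10 adjusted over the list alone), including the antibacterial phospholipase Pla2g2a at 3.61 ± 0.31 and the protease inhibitor Slpi at 2.98 ± 0.45. The mucosal defence list had camera adjusted p = 4.69e-05, and adjusted p = 0.302 with an estimated correlation. Reg3g, an antibacterial lectin of the gut lining, rose by 2.48 ± 0.74 (adjusted p = 0.0292, but 0.166 without day 2 replicate 2). Without day 2 replicate 2 the macrophage, cytokine and neutrophil counts were 7, 5 and 3, and without replicate 3 they were 8, 4 and 3. As deposited, camera called the macrophage list up too (adjusted p = 0.0171), but not the neutrophil (0.103), chemokine (0.977), cytokine (0.238) or mucosal defence (0.558) lists.

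Stress and tissue-remodelling genes followed on the same day. The haem-degrading enzyme Hmox1 rose by 2.87 ± 0.34 and mitochondrial superoxide dismutase, Sod2, by 1.30 ± 0.26, in a list of 26 oxidative stress genes of which 12 rose and 1 fell, the same counts when adjusted over the list alone. The oxidative stress list had camera adjusted p = 0.00346, and adjusted p = 0.302 with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, rose by 3.80 ± 0.53 and the membrane-bound protease Mmp14 by 1.56 ± 0.22, with 7 of 20 genes of that list up (7 adjusted over the list alone; adjusted p = 0.0225, 0.0981 without day 2 replicate 2, and adjusted p = 0.705 with an estimated correlation). Complement and coagulation genes rose in 9 of 23 cases (9 adjusted over the list alone), among them the C1 inhibitor Serping1 at 1.60 ± 0.22. The complement list had camera adjusted p = 1.97e-05, and adjusted p = 0.497 with an estimated correlation. Of 32 cell division genes 6 rose (6 adjusted over the list alone), among them the mitotic kinase Aurka at 0.99 ± 0.21. The cell division list had camera adjusted p = 0.0014, 0.0992 without day 2 replicate 3, and adjusted p = 0.825 with an estimated correlation. In day 2 replicates 1, 2 and 3 its mean minus the control mean was -0.01, 0.423 and 0.908, with 0.407 in the highest control array. Beside it T cell markers were at -0.323, -0.218 and 2.037, and B and plasma cell markers at -0.559, -0.74 and 2.011. Collagens and matrix proteins rose in 7 of 31 cases and fell in 1 (8 and 1 adjusted over the list alone); the proteoglycan biglycan, Bgn, was at 1.25 ± 0.20, whereas the chain of type I collagen Col1a1 was at 0.03 ± 0.39, which was not called. The collagen and matrix list had camera adjusted p = 0.0148, 0.477 without day 2 replicate 2, and adjusted p = 0.825 with an estimated correlation. Without day 2 replicate 2 the oxidative stress, metalloproteinase, cell division and collagen counts that rose were 5, 3, 2 and 2, without replicate 3 they were 5, 4, 1 and 2, and without replicate 1 cell division and collagens had 10 and 13. As deposited, camera called none of these 5 lists (adjusted p = 0.817 for oxidative stress and 0.212 for collagens, both pointing down, 0.936 for metalloproteinases, 0.243 for complement and 0.515 for cell division).

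Some transport, muscle and fatty acid oxidation genes were lower on day 2. Others were higher, a balance that the condition of both scales in part sets. Of 35 epithelial ion and water transport genes 4 fell and 3 rose (2 and 3 adjusted over the list alone). Slc16a1, a carrier of lactate and butyrate, fell by 1.09 ± 0.21, while Scnn1b, a subunit of the epithelial sodium channel, rose by 1.08 ± 0.26. The ion and water transport list had camera adjusted p = 0.0249, 0.203 without day 2 replicate 2, and adjusted p = 0.825 with an estimated correlation. In day 2 replicates 1, 2 and 3 its mean minus the control mean was 0.125, -0.795 and -0.663, and that of enterocyte markers 0.067, -0.758 and -0.519. The chloride and bicarbonate exchanger Slc26a3 fell by 1.66 ± 0.42 (adjusted p = 0.0119, but 0.094 without day 2 replicate 2). Smooth muscle markers fell in 4 of 16 cases (2 adjusted over the list alone), with Csrp1 at -1.10 ± 0.18 and Tagln, transgelin, at -0.84 ± 0.17. The smooth muscle list had camera adjusted p = 0.0149, 0.233 without day 2 replicate 3, and 0.825 with an estimated correlation. Acadm, which starts the oxidation of medium-chain fatty acids, fell by 1.06 ± 0.21, 1 of 29 fatty acid oxidation and ketogenesis genes that did, while 2 rose, the same counts when adjusted over the list alone. The fatty acid oxidation list had camera adjusted p = 0.0185, 0.115 without day 2 replicate 3, and adjusted p = 0.825 with an estimated correlation. The transport count that fell was 7, 1 and 1 without replicates 1, 2 and 3, and the smooth muscle count 1 without replicate 3. Leaving out day 2 replicate 3 brought the quantile-normalized counts to 1599 higher and 1458 lower, and leaving out replicate 2 to 1684 and 1648, against 3301 and 3513 without replicate 1. Retnla, a secreted resistin-like protein, fell by 4.10 ± 1.26 (adjusted p = 0.0327), a call that ended when any 1 of 6 arrays was left out, as with 0.144 without day 2 replicate 3.

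**Figure D3:**
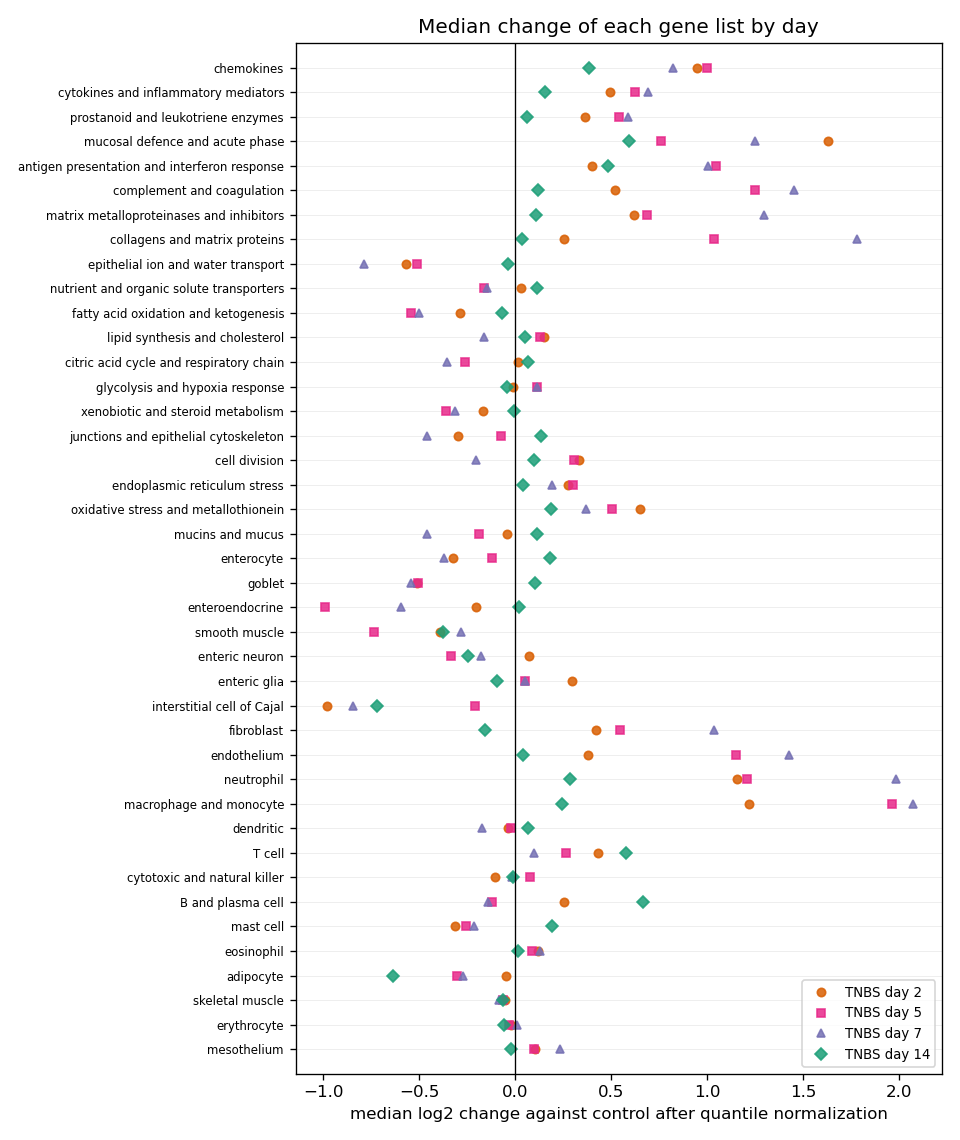
Median log2 change against control (quantile-normalized values) of the measured members of 41 gene and cell type lists, at each of the 4 days. Macrophage, matrix and endothelial lists are highest on days 5 and 7, as collagens and matrix proteins at 1.04 and 1.78, and all these medians are nearer to 0 on day 14.

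On day 5 the increases against control included vessel, matrix and interferon-response genes. Cxcl2 rose by 7.80 ± 0.55, S100a9 by 7.37 ± 0.52, S100a8 by 7.27 ± 0.61, Plek by 6.24 ± 0.65, Lcn2 by 6.05 ± 0.66 and Il1b by 5.89 ± 0.43 against control (limma adjusted p between 4.65e-07 and 1.90e-05). Decreases included Apoa1, an apolipoprotein of high-density lipoprotein, which fell by 4.50 ± 0.97, and the sodium and proton exchanger Slc9a3, which fell by 4.21 ± 0.73 (adjusted p = 0.00326 and 0.000691). Drc3, a subunit of the dynein regulatory complex of cilia, fell by 3.17 ± 0.58, the gluconeogenic enzyme Pck1 fell by 2.23 ± 0.43, and the small matrix proteoglycan Aspn fell by 2.55 ± 0.35. Quantile normalization gave 3762 probe sets higher and 4493 lower, of which 3762 and 338 were called on both scales.

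Matrix, endothelial and interferon groups had called members on day 5. Collagens and matrix proteins rose in 25 of 31 cases (26 adjusted over the list alone): Col1a1 by 1.72 ± 0.39, the basement-membrane collagen Col18a1 by 2.00 ± 0.28 and Bgn by 2.25 ± 0.20. The collagen and matrix list had camera adjusted p = 2.10e-09, and adjusted p = 0.625 with an estimated correlation. Without day 5 replicate 2 the count of collagens was 13, and without replicate 1 that of interferon response genes was 11. Endothelial markers rose in 9 of 14 cases (10 adjusted over the list alone), with the receptor kinase Tie1 at 1.92 ± 0.29, the vascular endothelial growth factor receptor Kdr at 1.40 ± 0.29 and Plvap, a protein of endothelial diaphragms, at 1.14 ± 0.18. The endothelial list had camera adjusted p = 5.84e-05, and adjusted p = 0.541 with an estimated correlation. Antigen presentation and interferon response genes rose in 17 of 28 cases (22 adjusted over the list alone). The interferon-induced Ifit3 was up by 4.40 ± 0.37, the peptide transporter Tap1 by 2.71 ± 0.32 and the interferon-induced GTPase Gbp2 by 2.29 ± 0.38. The interferon response list had camera adjusted p = 5.58e-09, and adjusted p = 0.443 with an estimated correlation. Fibroblast markers rose in 6 of 13 cases and fell in 1 (8 and 1 adjusted over the list alone), with the growth factor receptor Pdgfrb at 1.31 ± 0.26 and podoplanin, Pdpn, at 1.53 ± 0.28. The fibroblast list had camera adjusted p = 0.0125, and adjusted p = 0.713 with an estimated correlation.

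The macrophage, neutrophil, chemokine and cytokine lists again held rising genes on day 5. Macrophage and monocyte markers rose in 15 of 17 cases (16 adjusted over the list alone), including the fungal-glucan receptor Clec7a at 3.11 ± 0.36 and the immunoglobulin G receptor Fcgr3a at 1.83 ± 0.16. The macrophage list had camera adjusted p = 3.55e-11, and adjusted p = 0.302 with an estimated correlation. Neutrophil markers rose in 6 of 10 cases, and in 6 adjusted over the list alone, with Csf3r at 4.01 ± 0.45. The neutrophil list had camera adjusted p = 9.63e-05, and adjusted p = 0.39 with an estimated correlation. Of the chemokines 11 of 20 rose (12 adjusted over the list alone), with Ccl3 at 4.78 ± 0.52. The chemokine list had camera adjusted p = 1.86e-05, and adjusted p = 0.302 with an estimated correlation. Of the cytokines and mediators 12 of 23 rose (12 adjusted over the list alone), with Il1r2 at 5.59 ± 0.63 and tumour necrosis factor, Tnf, at 1.67 ± 0.36. The cytokine and mediator list had camera adjusted p = 9.63e-05, and adjusted p = 0.498 with an estimated correlation. The prostaglandin synthases Ptgs2 and Ptges rose by 5.35 ± 0.72 and 1.73 ± 0.35, in a list of 15 prostanoid and leukotriene enzymes of which 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0607). Fry, which tests whether a set moves on balance 1 way and does not compare it with other genes, gave adjusted p = 0.00113 for that list. Complement and coagulation genes rose in 13 of 23 cases (17 adjusted over the list alone; adjusted p = 3.84e-08, and adjusted p = 0.302 with an estimated correlation), and oxidative stress genes in 13 of 26, with 1 down (14 and 1 adjusted over the list alone; adjusted p = 0.00803, and adjusted p = 0.302 with an estimated correlation). Without day 5 replicate 2 the count of oxidative stress genes was 8. Hmox1 rose by 3.47 ± 0.34 and the complement protease C1s by 1.25 ± 0.17. As deposited, camera also called the macrophage, neutrophil, cytokine and complement lists up on day 5 (adjusted p = 0.000277, 0.0274, 0.0405 and 0.0118), but not the collagen (0.0687), endothelial (0.0582), interferon (0.0774), fibroblast (0.953), chemokine (0.449) or oxidative stress (0.728) lists.

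Transport, smooth muscle and fatty acid oxidation genes had falling members on day 5. Epithelial ion and water transport genes fell in 7 of 35 cases, with 0 up (7 and 0 adjusted over the list alone); besides Slc9a3, the sodium, potassium and chloride cotransporter Slc12a2 fell by 1.03 ± 0.18. The ion and water transport list had camera adjusted p = 0.0144, 0.143 without day 5 replicate 2, and adjusted p = 0.825 with an estimated correlation. Its means in day 5 replicates 1, 2 and 3 were -0.210, -1.114 and -0.602, beside 0.199, -0.705 and -0.231 for enterocyte markers. Smooth muscle markers fell in 7 of 16 cases, also adjusted over the list alone, with smoothelin, Smtn, at -1.73 ± 0.29, Csrp1 at -1.27 ± 0.18 and Tagln at -1.16 ± 0.17. The smooth muscle list had camera adjusted p = 6.22e-05, and 0.668 with an estimated correlation. Fatty acid oxidation genes rose in 2 cases and fell in 2, with the same counts adjusted over the list alone. The fatty acid oxidation list had camera adjusted p = 0.00206, 0.0798 without day 5 replicate 2, and adjusted p = 0.825 with an estimated correlation. Acadm fell by 1.16 ± 0.21. Ceacam1, a cell adhesion protein counted as an enterocyte marker, rose by 2.21 ± 0.48, while Muc2, the main secreted mucin, and Tff3, a goblet cell trefoil peptide, were at -0.53 ± 0.23 and -0.19 ± 0.15 and were not called. Without day 5 replicate 2 the counts that fell were 2 for transport and 3 for smooth muscle, and without replicate 3 transport had 4. Leaving out day 5 replicate 2 lowered the quantile-normalized counts to 2414 higher and 2707 lower. Of 99 named genes called on day 5, 12 lost the call without some single array, among them Slc26a3 (a fall by 1.50 ± 0.42, with adjusted p up to 0.0927) and interleukin-6, Il6 (at 1.86 ± 0.53, adjusted p 0.141 without day 5 replicate 2).

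Day 7 gave the largest values of many inflammatory and matrix genes against control. Cxcl2 rose by 8.37 ± 0.55, S100a8 by 7.78 ± 0.61, S100a9 by 7.59 ± 0.52, Lcn2 by 6.98 ± 0.66, Il1b by 6.62 ± 0.43, Il1r2 by 6.47 ± 0.63 and Plek by 6.44 ± 0.65 (n = 3 against 6, limma adjusted p between 3.04e-07 and 8.10e-06). Among the decreases were Sstr1, a somatostatin receptor, which fell by 2.51 ± 0.47, Amn, which fell by 2.26 ± 0.22, and the fucosyltransferase Fut1, which fell by 2.04 ± 0.29 (adjusted p = 0.00108, 5.83e-06 and 0.000124). Tgm3, a transglutaminase, was lower at -2.44 ± 0.61 and Akr1c15, an aldo-keto reductase, at -2.31 ± 0.66, calls that ended without day 7 replicate 2 (adjusted p = 0.0525 and 0.1). There were 3849 probe sets higher and 4951 lower after quantile normalization, 3849 and 331 of them on both scales. After quantile normalization the F test over the 4 days called 8642 probe sets. Of these 3646 had their largest deviation from control on day 7, against 1512, 2516 and 968 on days 2, 5 and 14. Day 2 had 3065 without its replicate 1. Of 726 also called by the F test among days, day 7 held 482 higher and 72 lower. Days 2, 5 and 14 held 26 and 13, 49 and 61, and 16 and 7. As deposited, where the offset lifts nearly all, day 7 had the fewest.

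Nearly every measured matrix gene was up on day 7. Collagens and matrix proteins rose in 30 of 31 cases, also adjusted over the list alone: Bgn by 2.79 ± 0.20, Col18a1 by 2.64 ± 0.28, Col1a1 by 2.29 ± 0.39 and Col6a2 by 1.85 ± 0.23. The collagen and matrix list had camera adjusted p = 4.35e-18, and adjusted p = 0.347 with an estimated correlation. Matrix metalloproteinases and their inhibitors rose in 15 of 20 cases, also adjusted over the list alone, with Timp1 at 3.25 ± 0.53, Mmp14 at 2.96 ± 0.22 and the neutrophil gelatinase Mmp9 at 2.99 ± 0.51. The metalloproteinase list had camera adjusted p = 4.25e-06, and adjusted p = 0.302 with an estimated correlation. Fibroblast markers rose in 10 of 13 cases, also adjusted over the list alone, among them Pdpn at 2.24 ± 0.28 and Pdgfrb at 1.72 ± 0.26. The fibroblast list had camera adjusted p = 1.17e-05, and adjusted p = 0.409 with an estimated correlation. Endothelial markers rose in 11 of 14 cases, with the same count adjusted over the list alone, and Kdr was at 1.83 ± 0.29. The endothelial list had camera adjusted p = 5.58e-06, and adjusted p = 0.443 with an estimated correlation. Of 5 mesothelial markers 2 rose, also adjusted over the list alone: mesothelin, Msln, by 2.32 ± 0.26 and the transcription factor Wt1 by 1.42 ± 0.18. The mesothelial list had camera adjusted p = 0.0398, 0.0727 without control replicate 6, and adjusted p = 0.541 with an estimated correlation.

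Macrophage and monocyte markers rose in 16 of 17 cases on day 7, also adjusted over the list alone, with Gpnmb at 4.17 ± 0.37 and Clec7a at 4.14 ± 0.36. The macrophage list had camera adjusted p = 8.93e-13, and adjusted p = 0.302 with an estimated correlation. Neutrophil markers rose in 6 of 10 cases, with the same count adjusted over the list alone; Csf3r was at 5.15 ± 0.45. The neutrophil list had camera adjusted p = 1.23e-05, and adjusted p = 0.302 with an estimated correlation. Chemokines rose in 9 of 20 cases, also adjusted over the list alone, with Ccl3 at 5.94 ± 0.52 and the monocyte-attracting Ccl9 at 4.70 ± 0.30 outside that list. The chemokine list had camera adjusted p = 1.97e-05, and adjusted p = 0.302 with an estimated correlation. Cytokines and mediators rose in 13 of 23 cases, also adjusted over the list alone, with Il6 at 2.90 ± 0.53, Tnf at 2.43 ± 0.36 and Il1rn at 4.07 ± 0.34. The cytokine and mediator list had camera adjusted p = 7.10e-06, and adjusted p = 0.382 with an estimated correlation. Complement and coagulation genes rose in 19 of 23 cases (21 adjusted over the list alone), with Serping1 at 2.32 ± 0.22. The complement list had camera adjusted p = 6.12e-12, and adjusted p = 0.302 with an estimated correlation. Antigen presentation and interferon response genes rose in 15 of 28 cases (16 adjusted over the list alone; adjusted p = 1.97e-05, and adjusted p = 0.66 with an estimated correlation), with Ifit3 at 5.49 ± 0.37; that count was 8 without day 7 replicate 1 or 3. Inducible nitric oxide synthase, Nos2, and interferon gamma, Ifng, were at -0.29 ± 0.27 and -0.01 ± 0.07 and were not called at any day. As deposited, the chemokine, interferon, fibroblast and mesothelial lists were not called on day 7 (adjusted p = 0.431, 0.555, 0.0793 and 0.134), and the other rising lists given here were, as collagens at 1.66e-05 and macrophage markers at 2.08e-05.

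Some epithelial and energy-metabolism genes were lower on day 7. Epithelial ion and water transport genes fell in 6 of 35 cases and rose in 0 (3 and 1 adjusted over the list alone). The water and glycerol channel Aqp3 fell by 1.75 ± 0.29, Slc16a1 fell by 1.38 ± 0.21 and Slc12a2 fell by 0.89 ± 0.18. The ion and water transport list had camera adjusted p = 0.000779, and adjusted p = 0.692 with an estimated correlation. Citric acid cycle and respiratory chain genes fell in 5 of 33 cases and rose in 1 (1 and 1 adjusted over the list alone), with the complex I subunit Ndufs1 at -0.94 ± 0.12 and cytochrome c1, Cyc1, at 0.60 ± 0.13. The respiratory chain list had camera adjusted p = 0.000121, and adjusted p = 0.713 with an estimated correlation. Fatty acid oxidation genes fell in 5 of 29 cases and rose in 2 (3 and 2 adjusted over the list alone; adjusted p = 0.00628, 0.197 without day 7 replicate 1, and adjusted p = 0.825 with an estimated correlation). Enterocyte markers fell in 4 of 18 cases (0 adjusted over the list alone), with the keratin Krt20 at -0.98 ± 0.25. The enterocyte list had camera adjusted p = 0.0356, 0.329 without day 7 replicate 1, and adjusted p = 0.825 with an estimated correlation. Muc3, a membrane mucin of the brush border, fell by 0.95 ± 0.22, whereas Car1, a carbonic anhydrase of the colon surface, and the water channel Aqp8 were at -0.30 ± 0.53 and -1.97 ± 0.72 and were not called. Of 99 named genes called on day 7, 13 lost the call without some single array, among them Krt20 (0.076 without day 7 replicate 1) and Slc26a3 (-1.47 ± 0.42, with 0.108 without the same array). Without day 7 replicate 1 the counts that fell were 2 for transport, 1 for the respiratory chain, 1 for fatty acid oxidation and 0 for enterocyte markers by limma, and without replicate 2 transport had 10. The quantile-normalized count of lower probe sets was 3279 without day 7 replicate 1.

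**Figure D4:**
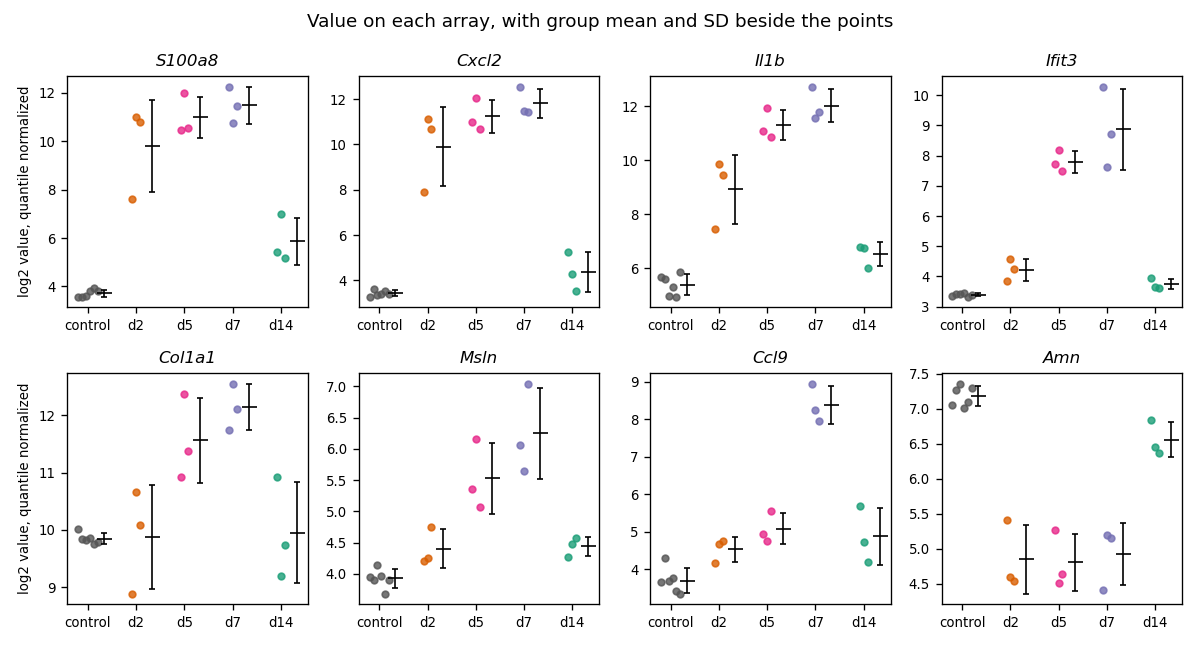
Quantile-normalized log2 level of 8 genes on each of the 18 arrays, by group, with the mean and SD of each group. S100a8, Cxcl2 and Il1b are raised on day 2 and highest on day 7, Ifit3, Col1a1 and Msln are higher on days 5 and 7 than on day 2, Ccl9 is highest on day 7, and Amn is low on days 2, 5 and 7.

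By day 14 most of the inflammatory genes were no longer called against control. S100a9 was still up by 2.78 ± 0.52 (n = 3 against 6, limma adjusted p = 0.00262), and Mmp14 and Bgn by 1.51 ± 0.22 and 1.14 ± 0.20 (adjusted p = 0.000487 and 0.00196). Cxcl2, Il1b, Lcn2, Ptgs2 and Timp1 were at 0.93 ± 0.55, 1.13 ± 0.43, 1.61 ± 0.66, 0.93 ± 0.72 and 0.42 ± 0.53, none of them called. Mark2, a kinase of microtubule-associated proteins, rose by 2.27 ± 0.18, close to its 2.18 ± 0.18 on day 2. The decreases included the nuclear phosphatase Ctdspl2, which fell by 1.69 ± 0.28, the translation factor Eif5a, which fell by 1.38 ± 0.14, and the circadian repressor Nr1d1, which fell by 1.73 ± 0.36 (adjusted p = 0.00102, 1.82e-05 and 0.0061). Mark2, Ctdspl2, Eif5a and Nr1d1 were called the same way at all 4 days and not in the F test among the days, a pattern that an offset between control and TNBS arrays would also give. Per3, another clock gene, fell by 1.62 ± 0.28. After quantile normalization 1741 probe sets were higher and 1891 lower, and 1741 and 42 were called on both scales. Of these, 55 and 1 were also called in the F test among the 4 TNBS days. On days 2, 5 and 7 those counts were 237 and 9, 477 and 18, and 527 and 25. The other calls cannot be told from an offset between control and TNBS arrays by that test.

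The list counts were small on day 14. Among 10 neutrophil markers 2 rose, also adjusted over the list alone (adjusted p = 0.071), and among 17 macrophage markers 1 did (0 adjusted over the list alone; adjusted p = 0.071). None of 20 chemokines was called by limma over all genes or adjusted over the list alone, and the list median was 0.38 (camera adjusted p = 0.064). Collagens and matrix proteins rose in 1 of 31 cases, also adjusted over the list alone, with Col1a1 at 0.11 ± 0.39 (adjusted p = 0.618). Antigen presentation and interferon response genes rose in 3 of 28 cases (5 adjusted over the list alone; adjusted p = 0.000677, 0.371 as deposited, and adjusted p = 0.713 with an estimated correlation). Its means minus the control mean in day 14 replicates 1, 2 and 3 were 0.552, 0.875 and 0.334, beside 1.298, 2.087 and 0.179 for B and plasma cell markers and 0.465, 1.151 and 0.272 for T cell markers, and in control replicate 2 the 3 lists were at 0.397, 1.616 and 0.579. Smooth muscle markers fell in 3 of 16 cases (2 adjusted over the list alone). Csrp1 was at -1.13 ± 0.18, called lower at all 4 days as an offset would also give, and Tagln at -0.89 ± 0.17. The list had adjusted p = 0.00506, 0.0536 without day 14 replicate 2, and 0.825 with an estimated correlation. The endoplasmic reticulum chaperones Pdia4 and Calr rose by 1.09 ± 0.24 and 0.61 ± 0.10. In its list of 25 stress genes 4 rose, also adjusted over the list alone (adjusted p = 0.459). Without day 14 replicate 2 the interferon, endoplasmic reticulum, macrophage and neutrophil counts were 0, 2, 0 and 1 by limma, and without replicate 3 the first 3 were 0, 2 and 2.

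The largest increase named on day 14 depended on single arrays. Glycam1, a ligand of L-selectin on lymph node venules, rose by 2.84 ± 0.84 and the shared cytokine receptor chain Il2rg by 2.29 ± 0.70 (adjusted p = 0.0393 and 0.044), but each call ended when any 1 of 7 arrays was left out, as with 0.237 and 0.229 without day 14 replicate 2. In control replicate 2 Glycam1 stood at 6.119, against a median of 4.776 in the other controls, and Il2rg at 7.024 against 4.922. S100a8 rose by 2.15 ± 0.61, a call that ended when any 1 of 6 arrays was left out (0.197 without day 14 replicate 2). Leaving out day 14 replicate 2 lowered the quantile-normalized counts to 908 higher and 864 lower, leaving out replicate 3 to 1067 and 1097, and leaving out replicate 1 took the lower count to 1160.

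The comparisons between days asked how the tissue changed from 1 time to the next, and no control array enters their differences. Between days 2 and 5, 3 probe sets rose and 0 fell as deposited in limma, with 1366 and 1476 at unadjusted p under 0.05. The genes with a single symbol were Ifit3, up by 3.54 ± 0.42, and Fcgr3a, up by 1.65 ± 0.19 (adjusted p = 0.00492 each, and 0.0511 for both without day 5 replicate 3). With only these 2 groups in the limma fit neither was called (adjusted p = 0.0799 for Ifit3 and 0.693 for Fcgr3a). Antigen presentation and interferon response genes had a median change of 0.83 between these days, with 1 of 28 up over all genes and 11 adjusted over the list alone (camera adjusted p = 1.08e-14, and adjusted p = 0.262 with an estimated correlation). Endothelial markers had a median of 0.93, with 0 called over all genes and 7 up and 1 down adjusted over the list alone (adjusted p = 2.24e-08, and adjusted p = 0.286 with an estimated correlation). The collagen and matrix list had a median of 0.62, with 0 called over all genes and 11 up adjusted over the list alone (adjusted p = 2.97e-13, and adjusted p = 0.366 with an estimated correlation). Respiratory chain and citric acid cycle genes went the other way, with a median of -0.26, 0 called over all genes and 3 down adjusted over the list alone (adjusted p = 3.50e-09, and adjusted p = 0.414 with an estimated correlation). Without day 5 replicate 1 there were 39 probe sets up and 9 down, and without day 5 replicate 3 there were 0 and 0.

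Between days 5 and 7, 5 probe sets rose and 1 fell, with 837 and 1112 at unadjusted p under 0.05 in limma. Ccl9 rose by 3.21 ± 0.36 and the integrin subunit Itga8 by 1.06 ± 0.12 (adjusted p = 0.002 and 0.00202). No single left-out array ended these calls, but with only the 2 groups in the limma fit neither was called (adjusted p = 0.521 and 0.826), and Itga8 was at 0.58 with adjusted p = 0.168 as the mean of its probe sets. Array weights gave 45 probe sets up and 32 down. The collagen and matrix list moved by a median of 0.59, with 0 called over all genes and 1 up adjusted over the list alone (camera adjusted p = 7.63e-16, and adjusted p = 0.297 with an estimated correlation). Smooth muscle markers moved up by a median of 0.55, with 0 called over all genes and 3 up adjusted over the list alone (adjusted p = 3.50e-09, and adjusted p = 0.309 with an estimated correlation). Cell division genes had a median of -0.43, with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 4.99e-09, and adjusted p = 0.452 with an estimated correlation). Without day 5 replicate 2 there were 34 probe sets up and 46 down, without day 7 replicate 2 there were 15 and 3, and without day 7 replicate 3 there were 8 and 0.

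The largest change between times lay between days 7 and 14, with 441 probe sets up and 956 down. Cxcl2 fell by 7.29 ± 0.61, Il1r2 fell by 6.05 ± 0.70, S100a8 fell by 5.44 ± 0.68 and Ifit3 fell by 5.15 ± 0.42 (n = 3 against 3, limma adjusted p between 3.60e-05 and 0.000439). Amn rose by 1.70 ± 0.26 (adjusted p = 0.00221). Guca2b, the gut peptide uroguanylin, and Crym, a thyroid hormone-binding protein, rose by 1.86 ± 0.48 and 1.69 ± 0.37, but their adjusted p were 0.151 and 0.0932 without day 7 replicate 1. Collagens and matrix proteins fell in 26 of 31 cases (31 adjusted over the list alone), with Col18a1 at -1.92 ± 0.30 (camera adjusted p = 1.15e-30, and adjusted p = 0.243 with an estimated correlation). Without day 7 replicate 1 or day 14 replicate 2 that count was 12, and without day 14 replicate 3 it was 14.

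Macrophage and monocyte markers fell in 12 of 17 cases between days 7 and 14 (16 adjusted over the list alone), with Clec7a at -3.79 ± 0.40 and Gpnmb at -2.98 ± 0.42 (adjusted p = 4.31e-19, and adjusted p = 0.223 with an estimated correlation). Neutrophil markers fell in 5 of 10 cases (6 adjusted over the list alone), with Csf3r at -4.94 ± 0.52 (adjusted p = 5.35e-08, and adjusted p = 0.243 with an estimated correlation). Chemokines fell in 8 of 20 cases, with 8 down and 1 up adjusted over the list alone (adjusted p = 6.31e-06, and adjusted p = 0.243 with an estimated correlation). Cytokines and mediators fell in 9 of 23 cases (10 adjusted over the list alone), with Il1b at -5.24 ± 0.47 (adjusted p = 1.33e-08, and adjusted p = 0.269 with an estimated correlation). Complement genes fell in 11 of 23 cases (20 adjusted over the list alone; adjusted p = 1.26e-18, and adjusted p = 0.223 with an estimated correlation), and metalloproteinases and inhibitors in 9 of 20 (14 adjusted over the list alone; adjusted p = 4.66e-10, and adjusted p = 0.243 with an estimated correlation). Serping1 fell by 1.51 ± 0.24 and Mmp14 fell by 1.39 ± 0.25. Fibroblast markers fell in 9 of 13 cases and endothelial markers in 5 of 14 (12 and 13 adjusted over the list alone), with Pdpn at -1.98 ± 0.31 and Kdr at -1.78 ± 0.32 (adjusted p = 6.47e-11 and 3.27e-10, and adjusted p = 0.243 and 0.261 with an estimated correlation). Without day 7 replicate 1 the fibroblast, endothelial and metalloproteinase counts were 3, 1 and 3, without day 14 replicate 2 they were 4, 3 and 3, and without day 14 replicate 3 they were 2, 2 and 3.

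Some energy and epithelial genes rose over the same interval. Citric acid cycle and respiratory chain genes rose in 11 of 33 cases, and in 30 adjusted over the list alone, with Dlst, a component of the 2-oxoglutarate dehydrogenase complex, at 0.61 ± 0.11 (adjusted p = 3.33e-13, and adjusted p = 0.297 with an estimated correlation). Without day 7 replicate 1 or day 14 replicate 3 the count over all genes was 3, and without day 14 replicates 1 and 2 it was 4 and 5. Epithelial ion and water transport genes rose in 5 of 35 cases (11 adjusted over the list alone; adjusted p = 6.50e-06, and adjusted p = 0.418 with an estimated correlation), but in 0 by limma over all genes without day 7 replicate 1 or day 14 replicate 3, as did junction genes. Junction and epithelial cytoskeleton genes rose in 4 of 31 cases and fell in 1 (19 and 1 adjusted over the list alone), and enterocyte markers rose in 1 of 18 (9 adjusted over the list alone). Their camera adjusted p were 1.02e-06 and 1.11e-05, and adjusted p = 0.418 and 0.424 with an estimated correlation. Of 70 named genes called between these days 30 lost the call without some single array, and the counts were 63 up and 375 down without day 7 replicate 1, 97 up without day 14 replicate 1, 165 and 480 without day 14 replicate 2, 130 and 399 without day 14 replicate 3, and 280 and 591 without day 7 replicate 3. With only the 2 groups in the fit there were 256 up and 576 down, and with array weights 946 and 1537.

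Between days 2 and 14 only 1 probe set rose and 5 fell, with 1512 and 1172 at unadjusted p under 0.05 in limma. Cxcl2 fell by 5.44 ± 0.61 and Hmox1 fell by 3.03 ± 0.37 (adjusted p = 0.00323 and 0.00364), but with only the 2 groups in the limma fit neither was called (adjusted p = 0.522 and 0.205). Pla2g2a fell by 2.99 ± 0.38 and Amn rose by 1.76 ± 0.26, with adjusted p = 0.0581 and 0.291 without day 2 replicate 2, and 0.0399 and 0.522 with only the 2 groups in the fit. Pla2g5, another secreted phospholipase, and Clec10a, a macrophage lectin, were at -1.18 ± 0.14 and -1.20 ± 0.17 (adjusted p = 0.00323 and 0.0122), and these 2 are named after their values were seen. Day 2 replicate 1 stood with day 14, so omitting it widens this gap by selection. Without it 205 probe sets were up and 175 down, and 6 chemokines, 6 mucosal defence genes, 6 macrophage and 4 neutrophil markers fell. S100a8, Timp1 and Il1b then fell by 4.82, 3.71 and 2.90, and Slc26a3 rose by 1.85. With all arrays the macrophage list had a median of -0.95 (adjusted p = 1.58e-11, and adjusted p = 0.243 with an estimated correlation), and 8 of its 17 genes were down adjusted over the list alone and 0 over all genes.

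Calls against control overlapped between days, which share their control arrays. After quantile normalization 2780 probe sets were higher and 3345 lower on both days 5 and 7, where independent lists would share 466 and 717, and 1338 were higher and 1331 lower on both days 2 and 14, where they would share 159 and 187. Unchanged groups simulated against the same controls shared 0 calls, but they hold no offset between control and TNBS arrays, so this is not a reference for the overlap. With the controls split into replicates 1 to 3 for the earlier and 4 to 6 for the later day, 1241 and 1106 were shared between days 5 and 7 (166 and 210 for independent lists) and 259 and 113 between days 2 and 14 (16 and 8), and this split keeps the offset. Of 1037 probe sets called the same way at all 4 days on both scales, such as those of Mark2, Eif5a and Csrp1, 29 were called by an F test among the 4 TNBS days, and 986 of the other 1008 were higher than control, an imbalance set by the condition of both scales. An F test among the 4 days called 727 probe sets as deposited and 760 after quantile normalization. As deposited it called 292 without day 14 replicate 3, 1042 without day 5 replicate 1, 1528 with array weights and 111 with replicate number as a block.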

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

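In 16 of 158 named genes and 5 of 41 lists 1 control array lay far from the other 5 by a Dixon test, which is expected by chance in about 1 of 20 groups tested. Control replicate 2 was high in leukocyte genes: Cd79b, a B cell receptor chain, was 7.883 (median of the other controls 4.454), Glycam1 6.119 (4.776), Il2rg 7.024 (4.922), Plek 6.215 (4.450) and Ptprcap, a partner of the phosphatase CD45, 6.872 (4.361), while Cd4, the helper T cell coreceptor, was low at 3.837 (4.162). Control replicate 1 stood apart in Cma1, mast cell chymase, at 3.719 (4.128), Col1a1 at 10.022 (9.819), Guca2b at 5.260 (6.272) and Hmox1 at 5.074 (5.977). Control replicate 3 was high in Scnn1b at 6.171 (5.081) and in the glial transcription factor Sox10 at 5.754 (5.439). Control replicate 5 was low in Drc3 at 7.802 (8.596) and in Nefl, a neurofilament, at 5.406 (6.148). Control replicate 6 was high in Kit, the receptor of pacemaker and mast cells, at 4.010 (3.674), and in the neuropeptide Vip at 8.470 (7.690). Among list means relative to the control mean, replicate 2 was high in B and plasma cell markers at 1.616 (-0.322), T cell markers at 0.579 (-0.092) and chemokines at 0.277 (-0.050), replicate 6 in fatty acid oxidation and ketogenesis at 0.149 (-0.025), and replicate 5 was low in enteric neuron markers at -0.453 (0.059).

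Of the tests of the shift of probe sets against control by a similar amount at all 4 days, those of separate normalization and of RNA degradation were chosen only after the result was seen. Normalization of control and TNBS arrays as 2 separate sets cannot be told apart from treatment or extraction acting on whole arrays: the gap between the highest control and the lowest TNBS array median was 0.726, 15.1 times the largest range of medians within a set (0.048), and each of the 3 would give such a gap. Probe sets of the same gene disagreed more in day 14 minus control than in day 14 minus day 7, by a ratio of 1.359 (interval 1.284 to 1.442, 4525 genes), in line with offsets of single probe sets between the 2 sets of arrays. RNA degradation in 1 set cannot be judged from these transcripts. The 3 prime minus 5 prime difference changed by -0.756 in beta-actin and by 0.557 in Gapdh, opposite directions that degradation alone would not give. Offsets of single probe sets could set the sign of each, however. The 5 prime, middle and 3 prime probe sets moved by -0.43, 0.326 and 0.127 in Gapdh and by 0.97, -0.349 and 0.215 in beta-actin, with no gradient along the transcript. How far treatment, extraction and normalization each contribute stays open. Treatment and the extraction entry coincide in every array, and whether the 2 sets were normalized separately is not known.

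Of the tests of day 2 replicate 1 lying nearer to the day 14 arrays, those of an exchange and of milder colitis were chosen only after the result was seen. An exchange with a day 14 array was argued against, since every day 14 array correlated better with the other day 14 arrays, by 0.0127 at the least and 0.0194 at the most. A day 14 sample under a wrong label cannot be told apart from a day 2 sample by position: on a scale from day 14 (0) to day 2 (1) its median was 0.213, with 0.111 for the highest day 14 array and a spread of 0.256 between day 14 arrays. Its neutrophil, chemokine and cytokine list means (1.003, 0.687 and 0.447) lay above every control array and below both other day 2 arrays in 3 of 3 lists, in line with milder colitis in this rat. The day 14 arrays also lie above the controls in the neutrophil list (0.569, 0.879 and 0.458), so this test does not separate the 2 readings.

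For epithelial ion and water transport genes, lower on day 7 than on day 14, both tests were written before their result was seen. Dilution by other cells of epithelial and muscle RNA to the same degree was not seen. The transport median was -0.903 and that of smooth muscle markers -0.018 (difference -0.886, interval -1.183 to -0.547). Both intervals in this paragraph resample genes and not rats, and the transport list means of day 7 replicates 1, 2 and 3 were -1.189, -0.564 and -0.615 relative to control. A separate change of muscle genes would also give this difference, so dilution is not excluded. A lower share of epithelial cells cannot be told apart from lower expression within them: the transport median was -0.903 and that of 10 enterocyte structural genes -0.590, a difference of -0.313 (interval -0.523 to 0.091).

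The splits of the arrays were planned before the result was seen. Against control the labelled split alone, 1 of 84, called as many probe sets as it did at each day and on each scale. After quantile normalization it called 5900 on day 2 (highest other split 45), 8255 on day 5 (2), 8800 on day 7 (20) and 3632 on day 14 (1), and as deposited 25866 (311), 25444 (2), 25203 (17) and 26951 (2). For the F test 1 of 100 groupings called as many, with 8642 against 2815 in the highest other. Splits that mix control and TNBS arrays put the offset between them into the spread within groups, and so call fewer probe sets whatever its cause. These tests therefore show that control and TNBS arrays differ, and cannot tell treatment from the offset. With 3 arrays against 3, 10 splits are too few for a share under 0.05. Day 14 against day 7 gave 1397 with 0 in the highest other (1 of 10), day 7 against day 5 gave 6 with 55 (3 of 10), and day 14 against day 2 gave 6 with 41 (2 of 10). Day 5 against day 2 gave 3 while a split that sets day 2 replicate 1 with day 5 replicates 1 and 3 gave 1035 (2 of 10), which points to a structure of these samples other than the day.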

How the results depend on the processing

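Alternatives on the quantile-normalized values were added after the data were seen, and unless said otherwise the cause of a changed value was not tested. Scale strongly moved the probe set counts against control. An estimated correlation ended all 131 list calls, 54 of them against control, of which 28 were lost as deposited. Single rats decided many calls in the comparisons between days, and the effect of array number on them was not tested. Of the named genes Alas2, Ccl9, Ccr3, Csf3r, Cxcl1, Cxcl2, Ifit3, Ifng, Il1rn, Il5ra, Il6, Kit, Mmp9, Ncr1, S100a8, Siglec5, Slc2a3, Tnf and Wt1 lie in the lowest 25% of control values (3.723 or lower), where background compresses differences and no detection call was used. The number of list results kept, weakened, strengthened and reversed was 319, 1, 8 and 0 with the mean of all probe sets, 309, 7, 12 and 0 with median centring, 295, 16, 17 and 0 with array weights, 244, 71, 13 and 0 with fry, and 197, 131, 0 and 0 with an estimated correlation.

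As deposited, the higher and lower counts of day 2 were 25703 and 163 against 2835 and 3065 after quantile normalization and 2533 and 9756 after median centring. Those of day 5 were 25104 and 340 against 3762 and 4493, and 3266 and 11149. Those of day 7 were 24872 and 331 against 3849 and 4951, and 3442 and 12419. Those of day 14 were 26909 and 42 against 1741 and 1891, and 2270 and 8774. The F test over the 4 days called 27326, 8642 and 15996. Quantile normalization gave 0 lower between days 5 and 7 and 2 higher between days 2 and 14. Days of largest deviation, in the order of the days, were 2621, 4026, 6382 and 2967 after median centring, and 7767, 6378, 5939 and 7242 as deposited. As deposited 5 list results reversed: chemokines on day 2 (adjusted p = 0.977), collagens on day 2 (0.212), oxidative stress on days 2 and 5 (0.817 and 0.728) and antigen presentation on day 14 (0.371). As deposited 18 gene values had the other sign, by the offset between the sets: Echs1 0.128 on day 2, Cldn12 0.167 on day 5, Tyms 0.274 on day 7, Pyy 0.007 on day 14, Neurod1 0.197, 0.053 and 0.120 on days 2, 5 and 14, Nefm 0.037 on day 2, Nefl 0.191 and 0.208 on days 2 and 14, Erbb3 0.342 and 0.022 on days 5 and 7, Itgae 0.446 on day 7, Pvalb 0.325, 0.289 and 0.359 on days 5, 7 and 14, and Slc4a1 0.461 and 0.397 on days 2 and 7.

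Testing fewer probe sets lowered the large counts against control by construction, while counts between days 2 and 14 rose from 1 higher and 5 lower. With the lowest 50% left out, 11025, 10654, 10509 and 12403 were higher on days 2, 5, 7 and 14, the F test called 12471, between days 5 and 7 there were 1 higher and 0 lower, and between days 2 and 14 there were 2 and 9. With the lowest 25% left out these were 0 lower, and 2 and 8. With 1 probe set per gene the higher and lower counts were 11203 and 95, 10815 and 199, 10669 and 210, and 11895 and 24, with 2 and 0 between days 5 and 7, 3 and 11 between days 2 and 14, and 12213 in the F test. On quantile-normalized values 1 probe set per gene gave 1648 and 1553, 2132 and 2406, 2126 and 2711, and 900 and 879, an F test of 4959, and largest deviations of 851, 1454, 2138 and 516. There, with the lowest 50% left out, 995 were lower on day 14, with 589 largest deviations.

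Array weights gave 68 lower on day 14, 45 and 32 between days 5 and 7, 946 and 1537 between days 7 and 14, 4 and 30 between days 2 and 14, and 1528 in the F test among days, and on quantile-normalized values 2778 and 3154 on day 14. With only the 2 groups compared there were 501 lower on day 7, 0 higher between days 2 and 5, 0 and 0 between days 5 and 7, 256 and 576 between days 7 and 14, and 1 lower between days 2 and 14. At adjusted p under 0.01, 68, 157, 133 and 21 were lower on the 4 days, 0 lower between days 5 and 7, 35 and 321 between days 7 and 14, and 0 higher between days 2 and 14; on quantile-normalized values 1386 and 1233, 2113 and 2281, 2410 and 2620, and 796 and 699.

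The labels do not say whether replicate numbers mark pairs, and the values do not settle it. Over 30 same-number pairs the correlation of deviations ran from -0.329 to 0.469 with 13 over 0.1. Its median was 0.063, against -0.013 for different-number pairs, and 9 of 15 arrays were nearest to their own number. With replicate number as a block, 1 was higher between days 2 and 5, 1 higher between days 5 and 7, 580 lower between days 7 and 14, 0 and 0 between days 2 and 14, and 111 were called among days. On quantile-normalized values the block gave 1843 and 1800 on day 2, 2989 lower on day 5, 1119 and 1018 on day 14, 4563 in the F test, and 847, 1277, 2001 and 438 largest deviations.

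Leaving out each array gave these lowest and highest counts as deposited. On day 2 there were 24224 to 25763 higher and 71 to 425 lower, on day 5 23702 to 25008 and 153 to 468, on day 7 23464 to 24714 and 174 to 337, and on day 14 24922 to 26733 and 25 to 47. Between days 2 and 5 there were 0 to 39 higher and 0 to 9 lower, between days 5 and 7 5 to 34 and 0 to 46, between days 7 and 14 63 to 393 and 375 to 1164, and between days 2 and 14 0 to 205 and 3 to 175. The F test called 26544 to 27820, and 292 to 1042 among days (lowest without day 14 replicate 3, highest without day 5 replicate 1). After quantile normalization the ranges were 1599 to 3301 and 1458 to 3513 on day 2, 2414 to 3619 and 2707 to 4302 on day 5, 2801 to 3793 and 3279 to 4862 on day 7, and 908 to 1642 and 864 to 1824 on day 14. There the F test called 7016 to 9575, and largest deviations ran from 1163 to 3065 on day 2 (highest without day 2 replicate 1), 1946 to 3367 on day 5, 2741 to 4085 on day 7 and 742 to 1034 on day 14.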

Other observations

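Nerve, hormone and other minor cell types of the wall had few members called on both scales, a condition that removes most falling genes. Of 9 enteroendocrine markers 1 rose and 1 fell on day 5, the same counts adjusted over the list alone, with a list median of -0.99 (camera adjusted p = 0.064), and the gut hormone Pyy was at -0.99 ± 0.22, which was not called on both scales. Of 16 enteric neuron markers none was called on day 14, where the list median was -0.25 (camera adjusted p = 0.026, 0.066 without day 14 replicate 3, and adjusted p = 0.668 with an estimated correlation). Of 3 markers of interstitial cells of Cajal, the pacemakers of gut muscle, none was called on day 7 (median -0.84, camera adjusted p = 0.333, and fry, a test against no change, 0.0119), and Ano1, their chloride channel, was at -0.86 ± 0.29. Glial markers rose in 1 of 6 cases on day 2, also adjusted over the list alone (median 0.30, adjusted p = 0.374). No erythrocyte marker of 5 was called the same way on both scales on any day (camera adjusted p = 0.979 on day 7). Slc4a1 was called lower after quantile normalization on days 2 and 7. As deposited it was higher, by 0.461 and 0.397 (limma adjusted p = 0.00037 and 0.00131), so a difference in blood content is left open. Of 16 skeletal muscle markers 1 rose on day 14, also adjusted over the list alone (median -0.07, adjusted p = 0.458). On day 7 1 of the skeletal muscle markers rose, also adjusted over the list alone: Acta1, skeletal muscle actin, at 2.50 ± 0.54 (adjusted p = 0.00293; list median -0.08, adjusted p = 0.493). Adipocyte markers fell in 2 of 13 cases and rose in 1 on day 5, also adjusted over the list alone (adjusted p = 0.302).

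Lymphocyte and granulocyte lists other than neutrophils had no camera call against control. T cell markers rose in 3 of 16 cases on day 7 (2 adjusted over the list alone, adjusted p = 0.352), among them Cd2, an adhesion molecule, at 0.93 ± 0.33 (adjusted p = 0.046, but 0.163 without day 7 replicate 1). Of 10 B and plasma cell markers none was called on day 14 (median 0.67, adjusted p = 0.0941), and the list means of the 3 day 14 arrays relative to control were 1.298, 2.087 and 0.179, beside 1.616 in control replicate 2 and 2.011 in day 2 replicate 3. Mast cell markers rose in 2 and fell in 1 of 13 cases on day 7 (2 and 0 adjusted over the list alone, adjusted p = 0.669), with the granule proteoglycan Srgn at 3.33 ± 0.42. Cytotoxic and natural killer markers rose in 2 of 10 cases on day 5, also adjusted over the list alone (adjusted p = 0.352), dendritic markers in 1 of 7, also adjusted over the list alone (median -0.02, camera direction up with adjusted p = 0.972), and eosinophil markers in 1 of 5 on day 7 (0 adjusted over the list alone, adjusted p = 0.248).

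Metabolic lists also held called members. Glycolysis and hypoxia response genes rose in 8 of 23 cases on day 5, also adjusted over the list alone (camera adjusted p = 0.0225, 0.0956 without day 5 replicate 2, 0.944 as deposited, and adjusted p = 0.66 with an estimated correlation), among them the glucose transporter Slc2a3 at 2.44 ± 0.40 and the lactate exporter Slc16a3 at 1.55 ± 0.30. Lipid and cholesterol synthesis genes rose in 4 of 22 cases on day 14, also adjusted over the list alone (adjusted p = 0.278), among them mevalonate kinase, Mvk, at 0.64 ± 0.13. Xenobiotic and steroid metabolism genes rose in 4 and fell in 1 of 45 cases on day 7, also adjusted over the list alone (adjusted p = 0.226), with the cytochrome reductase Por at 1.00 ± 0.14. Nutrient and solute transporters rose in 7 of 31 cases on day 5, also adjusted over the list alone, although the list median was -0.16 and camera pointed up (adjusted p = 0.82). Mucin genes rose in 1 and fell in 1 of 15 cases on day 5, also adjusted over the list alone (adjusted p = 0.493), and goblet markers fell in 1 of 8 on day 7 (0 adjusted over the list alone, adjusted p = 0.278). Of 32 spike-in tests, 2 had an unadjusted exact permutation p under 0.05, but spike-ins moved together within a day, so the tests are not independent. On day 7 dap was 0.930 higher (exact p = 0.048), thr and phe were 0.926 and 0.762 higher (exact p = 0.071 each), and lys was 0.436 higher. On day 14 bioD was lower by 0.445 (exact p = 0.048), and bioB, bioC and cre were at -0.605, -0.522 and -0.275. All spike-ins had lower means on day 14 than on day 7, such as bioD at 10.682 ± 0.162 against 11.277 ± 0.193 (SD, n = 3). Whether this difference bears on the calls between days 7 and 14 was not tested. No spike-in had all arrays of a day above all controls.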
